A study of Mus musculus with 4 samples.

How the data were processed

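RNA was sequenced from mouse T-helper 17 (Th17) cells of strain C57BL/6NJ, in 4 libraries that the labels number as biological replicates 1 to 4 of 1 group. Th17 cells are CD4 T cells that produce interleukin 17. The labels tie the libraries to different biosamples and to 1 shared donor identifier. They do not say whether the biosamples came from separate animals or cultures, so every SD and p-value measures only the spread between these libraries. Sex is marked as not collected and age as unknown in the labels. The assay title in the labels is total RNA-seq, and the library protocol that the labels link is named for poly(A)+ RNA. The labels give no time point. The output names in the file headers carry a tag of 2 hours in all 4 files, without saying from which event the hours were counted, and their replicate numbers are those of the labels.

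The deposited values are raw fragment counts per gene, made by the authors with featureCounts 1.4.6-p4 on GENCODE mouse release M13 exons, per the file headers. The options recorded there count read pairs as fragments, require both ends to be mapped and use reverse strandedness (option value 2). No option for fragments with several alignments or overlapping several genes was recorded, so such fragments were not counted. The alignment file names in the headers carry the name of the STAR aligner, whose version is not given in the sources used here, and the labels name the mm10 assembly. Genes with near-identical copies are undercounted by this rule, and antisense genes are separated by the strand setting. The union exon length of each gene was taken from the same deposited tables.

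Expected counts and TPM had been anticipated before the data were examined. The files held whole counts, so TPM, FPKM and CPM (counts scaled to a library total of 1e6) were computed here from the counts and the exon lengths, and no rounding was needed. TPM of very short genes is inflated by the length division. Of 50600 gene identifiers, 50376 were matched to a symbol of GENCODE mouse release M21 by the identifier without its version, and 224 were not; these took at most 0.00945% of the counts of a library. Coordinates are those of the files (mm10, M13). Biotypes are those of release M21. To mark genes that share sequence, the percent of each named gene's distinct 31-mers that also occurs in a transcript of another gene was computed from the M21 transcripts.

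Total counts were 36298276, 40652146, 26953724 and 25847970 in replicates 1 to 4. In these libraries 3 counts, the upper limit that a count of 0 allows, correspond to 0.0826, 0.0738, 0.111 and 0.116 CPM. Intervals on shares of counts in 1 library are 95% Wilson intervals. Intervals and limits cover counting error only, since no molecular identifiers were counted. No pair of libraries held identical values, and the chi-square per degree of freedom between libraries was 15.3 to 49.0, so each was used as 1 replicate.

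Levels are reported as TPM, mean ± SD over n = 4 libraries. For 29 gene lists fixed before the data were examined, the median over members of log2(TPM + 1) was taken per library. The Th17 regulator list and the list of Th17 effectors and receptors were each compared with 5 lists of other helper or naive T cells, within each library, after members shared by both lists were left out. In addition, 10 pairs of genes were compared, of which 6 are reported here. Both families used an exact two-sided sign-flip permutation test over the 4 libraries with Benjamini-Hochberg adjustment over the 10 contrasts of each family; the smallest p this design allows is 0.13, so no contrast could pass 0.05. The median of a list was also set against 10000 random lists of the same size from 21764 protein coding genes, as a description without a p-value.

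Variation between the libraries was modelled on the counts with edgeR 4.0.16 in R 4.3.3, with an intercept only, its expression filter (11567 genes kept) and TMM normalization. A gene was called as varying beyond the trend when its negative binomial deviance at the trended dispersion, against a chi-square distribution with 3 degrees of freedom, had a Benjamini-Hochberg adjusted p under 0.05. Because there is 1 group, no test between groups was made and the quasi-likelihood test of a coefficient did not apply. List members among the varying genes were counted with a one-sided Fisher's exact test, adjusted over the 29 lists. The step was tested on simulated counts for 11567 genes at the measured means, library sizes and trend. Of 100 genes raised 4-fold in 1 library it recovered 97%, of 100 genes raised 2-fold it recovered 36%, and it called 1 of 11367 unchanged genes. The unchanged genes were drawn at the trended dispersion itself, which the test assumes. The simulation therefore cannot show how often real genes, whose dispersions scatter around the trend, are called without cause. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

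The genes named were chosen by a rule written before the data were examined. It takes the genes of the pair contrasts, up to 6 members of each list with the highest mean TPM and up to 3 with the lowest, and the 10 nuclear genes with the highest mean TPM. It also takes the 20 genes with the widest log2 CPM range among varying genes with a mean TPM of 1 or more, each list member that varies, and any member of the sex-linked and polyadenylation-independent lists. Levels are not given for every gene that the rule takes. Genes named outside the rule are marked as chosen after their values were seen. Alternatives planned beforehand were other pseudocounts, units, thresholds, filters, backgrounds and normalizations, DESeq2 1.42.0 dispersion outliers, Holm adjustment and leaving out each replicate. A filter on a mean count of 10 or more, TPM without genes shorter than 200 bp, and leaving out each replicate in the count of varying list members were added after the data were seen.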

Results

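Gene expression was measured by RNA sequencing in mouse Th17 cells, as fragment counts per gene in 4 libraries of 1 group with total counts of 36298276, 40652146, 26953724 and 25847970 in replicates 1 to 4. A mean of 11842 ± 298 genes per library reached 1 TPM (SD, n = 4), and 10895 genes did so in every library, of which 9503 were protein coding. Across genes, the Pearson correlation of log2(TPM + 1) was 0.990 to 0.994 over the 6 library pairs and the Spearman correlation 0.916 to 0.919; genes are not independent replicates. All levels below are mean TPM ± SD over n = 4 libraries. With 1 group, the design allows comparisons of genes and gene lists within libraries and of libraries with each other.

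The first question was how strongly the libraries carried Th17 genes. Il17a, the signature cytokine of the lineage, stood low at 5.65 ± 1.20 TPM. Il17f stood at 12.4 ± 5.91 TPM, Il21 at 7.79 ± 1.73 TPM and Il22 at 0.601 ± 0.617 TPM. The transcription factors that act earlier in the lineage or in many activated T cells stood far higher, with Irf4 at 1856 ± 292 TPM, Fosl2 at 1308 ± 102 TPM, Batf at 684 ± 55.8 TPM, Stat3 at 599 ± 37.2 TPM and Hif1a at 522 ± 38.0 TPM. The nuclear receptor gene Rora stood at 9.82 ± 2.49 TPM and Ahr, the aryl hydrocarbon receptor, at 7.85 ± 1.27 TPM.

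All 12 Th17 regulators had a mean of 1 TPM or more, but only 3 of the 14 Th17 effectors and receptors did: Il17f, Il21 and Il17a. The remaining effectors included Il10 at 0.946 ± 0.370 TPM, Il9 at 0.948 ± 0.547 TPM and Il1r1 at 0.942 ± 0.273 TPM. The receptors Ccr6 (0.207 ± 0.177 TPM) and Il23r (0.132 ± 0.124 TPM) rested on 15 and 11 counts over the 4 libraries. Il17a rested on 245 counts and Il22 on 23, and 53.6% of the 31-mers of Il22 also occur in another gene, so its level is uncertain. The median regulator lay above all 10000 random lists (percentile 100), and the median effector at percentile 55.7; among genes of at least 0.1 mean TPM alone the effectors lay at percentile 0.29. Il17a lies on chromosome 1 from 20730905 to 20734496 and Il17f on chromosome 1 from 20777146 to 20790617 in mm10; the counts cover their annotated exons.

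**Figure D1:**
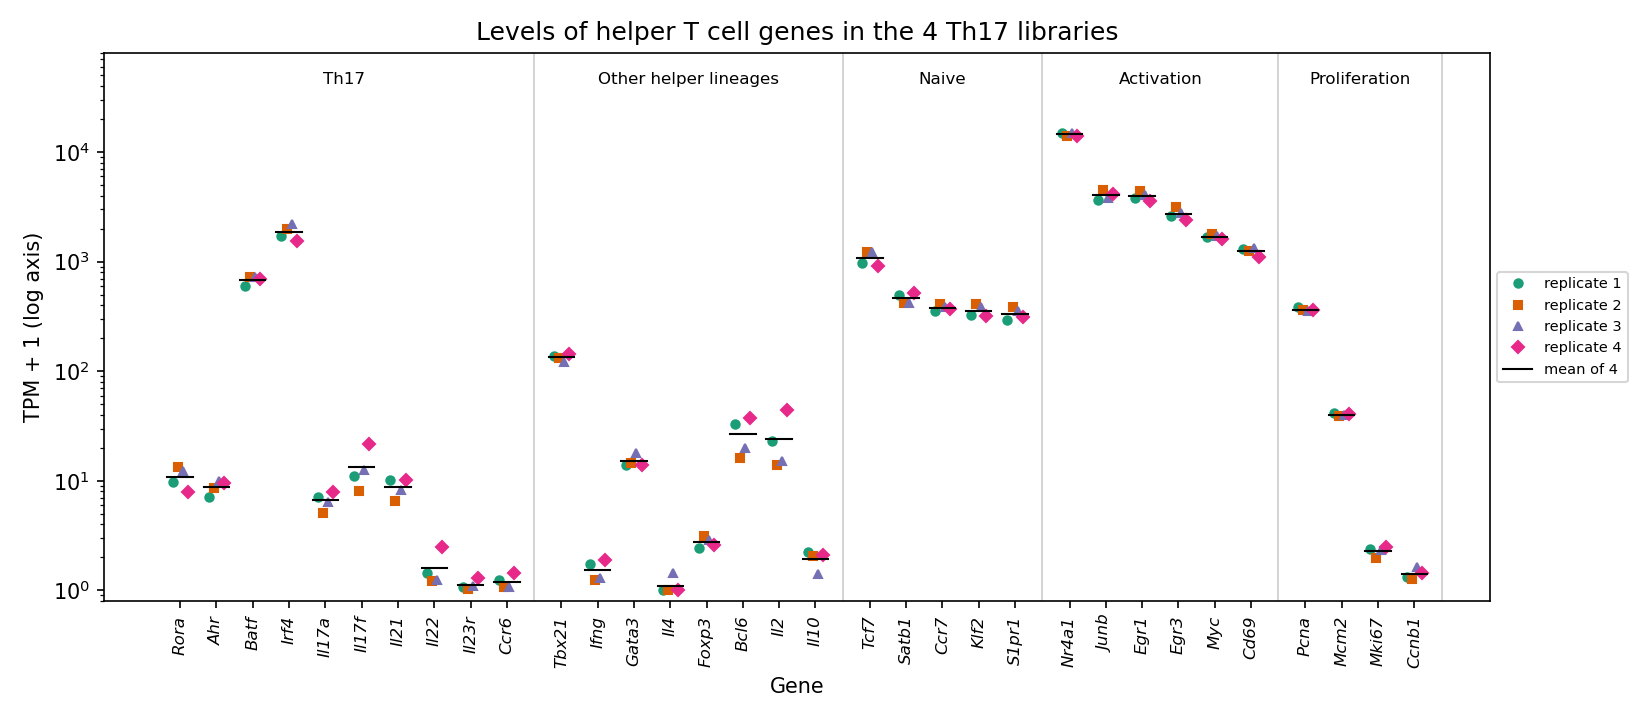
TPM plus a pseudocount of 1 on a log axis for genes of the Th17, other helper, naive, activation and proliferation lists. Each symbol is 1 of the 4 Th17 libraries and each black line the mean of the 4 values; Il17a averaged 5.65 TPM, Tbx21 133 TPM and Nr4a1 14458 TPM.

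The lineage regulators and cytokines of other helper cells were set against these genes. Tbx21, which encodes the Th1 regulator T-bet, stood at 133 ± 8.29 TPM, Gata3, the Th2 regulator, at 14.1 ± 1.94 TPM, Bcl6, the follicular helper regulator, at 25.6 ± 10.1 TPM and Foxp3, the regulatory T cell factor, at 1.77 ± 0.290 TPM. Among the cytokines, Il17a exceeded Ifng (0.548 ± 0.318 TPM) by a mean log2(TPM + 1) difference of 2.11 ± 0.13, Il4 (4 counts in all) by 2.58 ± 0.39, Il10 by 1.78 ± 0.38 and Il22 by 2.10 ± 0.32 in 4 of 4 libraries. It lay below Il2, the growth factor of activated T cells (23.1 ± 14.2 TPM), by -1.71 ± 0.54 and below Il17f by -0.94 ± 0.38 in 4 of 4 libraries. Each of these differences had p = 0.13 (adjusted p = 0.139) in the exact sign-flip permutation test, the smallest it can give with 4 libraries.

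Among the lists of other helper lineages, 9 of 12 Th1 genes, 4 of 10 Th2 genes, 7 of 10 Treg genes and 7 of 8 Tfh genes had a mean of 1 TPM or more. Th1 members other than Tbx21 included Stat4 at 64.8 ± 4.82 TPM, Fasl at 58.9 ± 4.75 TPM and Il18r1 at 30.7 ± 7.39 TPM. The Th2 list was led by Stat6 (256 ± 28.4 TPM) and the chemokine receptor Ccr8 (249 ± 54.6 TPM), while Il5 had 1 count in all. Treg members included Tnfrsf18 (116 ± 10.6 TPM), Ikzf4 (113 ± 22.6 TPM) and Ctla4 (78.7 ± 13.6 TPM), and Tfh members Btla (355 ± 43.9 TPM), Icos (285 ± 9.15 TPM), Pdcd1 (153 ± 35.0 TPM) and Cxcr5 (64.2 ± 5.19 TPM). The median Th17 regulator exceeded the median Th1, Th2, Treg and Tfh gene by 4.70 ± 0.17, 6.51 ± 0.18, 3.09 ± 0.29 and 1.47 ± 0.36 on the log2(TPM + 1) scale in 4 of 4 libraries. The median Th17 effector or receptor lay below the Th1, Treg and Tfh medians by -1.48 ± 0.23, -3.09 ± 0.32 and -4.70 ± 0.05 in 4 of 4 libraries, and above the Th2 median by 0.33 ± 0.30 in 3 of 4. The exact sign-flip permutation test gave p = 0.13 (adjusted p = 0.139) for each but the last, which had p = 0.25. With only members of at least 1 TPM, the effector contrasts with Th1 and Th2 turned to 0.24 and -2.77, and those with Tfh and with Treg were -2.91 and -3.01. The regulator contrasts with Th1, Th2, Treg and Tfh were then 3.94, 0.93, 0.69 and 0.79, so the sizes with Th2, Treg and Tfh rest largely on low members of those lists.

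Genes of naive and memory T cells stood high in every library. Tcf7, a transcription factor of resting T cells, stood at 1080.5 ± 159 TPM, Satb1 at 460.4 ± 50.6 TPM, the lymph node homing receptor Ccr7 at 378 ± 24.9 TPM, Klf2 at 356 ± 44.1 TPM, S1pr1 at 335 ± 40.1 TPM and Il7r at 204 ± 12.0 TPM. The lowest 3 of the 10 members were Lef1 at 120.0 ± 18.2 TPM, Foxp1 at 70.0 ± 2.71 TPM and Bach2 at 61.3 ± 9.70 TPM. The list median lay above all 10000 random lists. It exceeded the median Th17 regulator and the median Th17 effector in 4 of 4 libraries; the regulator and effector medians minus the naive median were -1.22 ± 0.22 and -7.40 ± 0.37 (the latter -4.92 with only members of at least 1 TPM), each with p = 0.13 (adjusted p = 0.139, exact sign-flip permutation test).

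Immediate early and activation genes were among the most abundant transcripts. Nr4a1, an orphan nuclear receptor induced within minutes to hours of T cell receptor signalling, stood at 14458 ± 505 TPM and took 1.05 ± 0.0171% of all counts; among nuclear genes with a symbol only Eef1a1 had a higher mean (14744 ± 1146 TPM). Junb stood at 4039 ± 369 TPM, Egr1 at 3965 ± 359 TPM, Egr3 at 2735 ± 309 TPM, Ier2 at 2373 ± 284 TPM, Myc at 1691 ± 68.4 TPM, Egr2 at 1324 ± 144 TPM and the early surface marker Cd69 at 1243 ± 92.3 TPM. All 12 members of the activation list and all 12 of the immediate early and heat shock list had a mean of 1 TPM or more, and the immediate early median lay above all 10000 random lists. Later or effector activation markers stood lower, with Cd44 at 15.4 ± 2.11 TPM and Tnfrsf9 at 7.62 ± 0.669 TPM. The heat shock genes in the same list included Dnajb1 at 202 ± 23.8 TPM, Hsph1 at 59.7 ± 18.3 TPM, Hspa1b at 8.997 ± 4.59 TPM and Hspa1a at 4.39 ± 2.58 TPM; the last 2 share 68.1% and 70.1% of their 31-mers with other genes, so their levels are uncertain.

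The T cell receptor complex was well represented, with 15 of 15 members above 1 TPM and a median above all 10000 random lists. Trac stood at 3565 ± 251 TPM, Cd2 at 1572 ± 95.3 TPM, Lck at 1175 ± 37.8 TPM and Lat at 873 ± 32.7 TPM, and the lowest member was Cd28 at 158 ± 16.4 TPM. Cd4, named here after its value was seen, stood at 364 ± 35.1 TPM. Of the 8 inhibitory receptors 6 reached 1 TPM. The highest of the 8 was Cd5 at 463 ± 29.3 TPM, and the lowest was Havcr2, below 1 TPM with 5 counts in all. Of the 15 genes of Th17 cytokine signalling 13 reached 1 TPM; the interleukin 6 receptor chains Il6st (390.5 ± 31.6 TPM) and Il6ra (238 ± 8.01 TPM), Tgfbr2 (243 ± 29.4 TPM), Il21r (584 ± 53.0 TPM), Jak1 (683 ± 18.3 TPM) and the feedback inhibitor Socs3 (908 ± 138 TPM) led, and Il12rb1 stood at 1.19 ± 0.760 TPM. In the fixed lists for the pathogenic and nonpathogenic Th17 signatures, 7 of 13 and 4 of 7 members reached 1 TPM. Pathogenic members included Icos and Tbx21 but also Ccl4 at 14.6 ± 4.02 TPM and Csf2 with 9 counts in all, and nonpathogenic members included Il6st, Ikzf3 at 66.7 ± 9.97 TPM and Maf at 13.8 ± 1.57 TPM. Of 16 homing receptors 13 reached 1 TPM, led by Selplg (469 ± 59.1 TPM) and Itgb7 (377 ± 48.6 TPM), while Itgae stood at 0.2003 ± 0.0607 TPM.

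**Figure D2:**
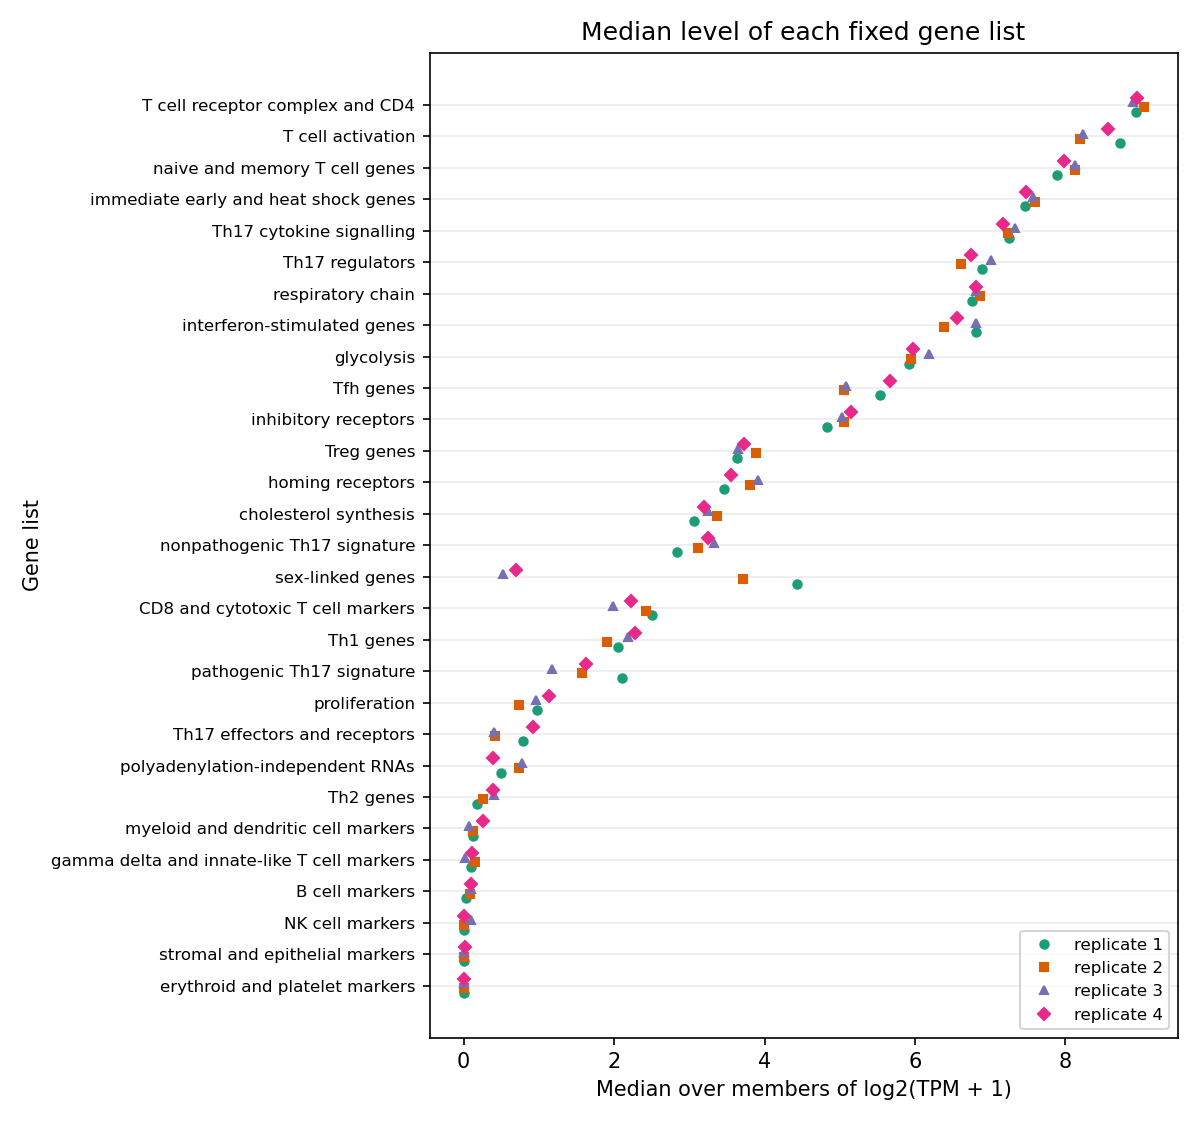
Median over members of log2(TPM + 1) for each of the 29 gene lists. Each symbol is 1 of the 4 Th17 libraries; the T cell receptor complex list has the highest mean of the 4 medians (8.95) and the erythroid and platelet list lies at 0.

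Proliferation genes stood low apart from those of DNA replication licensing and repair. Pcna stood at 365 ± 12.3 TPM, Mcm2 at 39.2 ± 0.996 TPM and Mcm5 at 34.8 ± 2.14 TPM, against Top2a at 6.26 ± 0.821 TPM and Mki67, the marker of cycling cells, at 1.29 ± 0.218 TPM. The mitotic genes Ccnb1 (0.411 ± 0.158 TPM), Bub1 (0.3995 ± 0.157 TPM) and Aurkb (0.312 ± 0.127 TPM) were lowest; 6 of 13 members reached 1 TPM and the list median lay at percentile 63.15 of random lists, or at 0.21 among genes of at least 0.1 mean TPM alone. All 15 glycolysis genes reached 1 TPM, from Ldha at 1839 ± 201 TPM and Pkm at 349 ± 13.8 TPM to Slc16a3 at 2.69 ± 0.717 TPM. Pkm shares 34.7% of its 31-mers with other genes and Gapdh (235 ± 16.6 TPM) 28.1%, so both are uncertain. All 13 respiratory chain genes (Cox4i1 at 459 ± 27.8 TPM, Uqcrc2 at 178 ± 10.98 TPM) and all 12 cholesterol synthesis genes (Insig1 at 141 ± 25.0 TPM, Lss at 2.18 ± 0.649 TPM) did so as well. Interferon-stimulated genes were also present, 12 of 12 above 1 TPM, with Isg15 at 406 ± 69.6 TPM, Ifit1 at 247 ± 49.8 TPM, Zbp1 at 246 ± 17.9 TPM and Mx1 at 1.81 ± 0.560 TPM. Mitochondrially encoded genes took 2.18 ± 0.174% of counts and ribosomal protein genes 5.90 ± 0.646%.

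Markers of other cell types stood low, with single exceptions. The median member of the B cell, myeloid and dendritic, NK, and stromal and epithelial lists stood at 0.0692, 0.214, 0.0280 and 0.0231 TPM, and that of the gamma delta and innate-like T cell list at 0.0881 TPM. Among B cell markers the exceptions at 1 TPM or more were Ighm (138 ± 12.6 TPM), Igkc (1.301 ± 0.571 TPM) and Cd79a (1.15 ± 0.516 TPM). Those of the myeloid and dendritic list were Cd74 (10.7 ± 1.27 TPM), Cd68 (10.4 ± 5.33 TPM) and H2-Aa (1.19 ± 0.555 TPM). Pecam1 (78.6 ± 8.38 TPM), Epcam (6.71 ± 1.27 TPM) and Col1a1 (1.35 ± 0.296 TPM) were those of the stromal and epithelial list. The NK list held Gzma (3.14 ± 1.09 TPM) and Eomes (1.12 ± 0.345 TPM), and the gamma delta list Trdc (3.39 ± 0.396 TPM). All 8 erythroid and platelet genes had 0 counts in every library, which allows up to 0.116 CPM each in the shallowest library; the globin genes among them are near-identical copies whose shared fragments were not counted. Of the 9 CD8 and cytotoxic genes 6 reached 1 TPM. Runx3 stood at 59.7 ± 6.71 TPM, Prf1 at 47.9 ± 7.66 TPM and Cd8b1 at 27.0 ± 4.86 TPM, whereas Cd8a, which encodes the partner chain, stood at 0.216 ± 0.184 TPM on 32 counts.

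Histone genes chosen by symbol as replication-dependent, a class whose mRNAs mostly lack a poly(A) tail, took 0.00384 ± 0.000574% of the counts. The small RNAs Rn7sk, Rmrp, Rpph1 and Terc took together 0.000406 ± 0.000142%. Hist1h1c led the histones with 40.1 ± 7.93 TPM and 2435 counts in all. Whether any histone counts came from polyadenylated transcripts was not tested. Rn7sk had 404 counts in all, Rmrp 68, Rpph1 32 and Terc 20, and Rn7sk, Rmrp and Rpph1 share 72.8%, 100% and 70.2% of their 31-mers with other genes. Rn7s1 and Rn7s2 had 0 counts and share 100% each. Shared fragments were not counted, so the share of these small RNAs is a lower limit. The most abundant nuclear genes included B2m at 11258 ± 1096 TPM, Rplp1 at 11903 ± 1434 TPM and Gm23935, a 57 bp microRNA model at 13368 ± 3084 TPM that rests on 29840 counts and is inflated by its length. Eef1a1, Rplp1 and Gm23935 share 51.5%, 75.1% and 100% of their 31-mers with other genes, so their levels are uncertain.

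Sex-linked genes divided the libraries. Xist, transcribed from the inactive X chromosome, stood at 0.791, 0.602, 142 and 76.5 TPM in replicates 1, 2, 3 and 4. The Y-linked Ddx3y stood at 305, 213, 0.914 and 1.39 TPM, Eif2s3y at 64.9, 71.2, 0.444 and 0.622 TPM, Kdm5d at 9.88, 8.04, 0.122 and 0.0853 TPM, and Uty at 20.6, 12.1, 0.108 and 0.0925 TPM in the same order. Xist, Ddx3y, Eif2s3y and Kdm5d had the 4 widest ranges among genes of at least 1 mean TPM that varied beyond the trend (edgeR adjusted p from 2.1e-174 to 1.5e-94). Uty was not tested with the main filter because its counts were low in replicates 3 and 4. Xist lies on chromosome X from 103460375 to 103483217 and Ddx3y on chromosome Y from 1260771 to 1286629.

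The last question was which other genes differed between the replicates by more than genes of like abundance. Cytokine and activation genes were among them: Il2 stood at 21.9, 12.9, 14.2 and 43.6 TPM in replicates 1, 2, 3 and 4 (edgeR adjusted p = 7.3e-05), Il2ra, its high-affinity receptor chain, at 95.8, 57.4, 65.6 and 118 TPM (adjusted p = 0.0055), Bcl6 at 31.7, 15.3, 18.9 and 36.4 TPM (adjusted p = 9.7e-05) and Il17f at 10.2, 7.04, 11.7 and 20.8 TPM (adjusted p = 0.017). The nuclear long noncoding RNA Malat1, on chromosome 19 from 5795690 to 5802672, stood at 426.5, 209, 795 and 188 TPM (adjusted p = 5.5e-10). Neat1, its neighbour, named here after its values were seen, stood at 34.8, 26.04, 58.2 and 20.7 TPM (adjusted p = 0.0028). The stress-induced chaperone genes Hspa1a and Hspa1b stood at 1.60, 7.83, 3.83 and 4.32 TPM and at 3.97, 14.7, 7.06 and 10.2 TPM (adjusted p = 0.0028 and 0.00049).

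In total 94 of 11567 tested genes varied beyond the trend, 0.813% of those tested, and the common biological coefficient of variation was 15.1%. They comprised 58 protein coding genes, 13 unconfirmed transcript models (biotype TEC), 11 lincRNAs and 4 sense intronic genes, with the rest in 5 smaller biotypes. In 57 of the 94 genes the 2 highest libraries were replicates 1 and 3, and in 21 they were replicates 1 and 4; over all tested genes these pairs were highest in 20.9% and 20.7%. Of the fixed lists, the sex-linked list (4 of 4 tested members, adjusted p = 1.2e-07), the activation list (Il2 and Il2ra, 2 of 12, adjusted p = 0.0395) and the immediate early and heat shock list (Hspa1a and Hspa1b, 2 of 12, adjusted p = 0.0395) held more varying genes than other tested genes in the one-sided Fisher's exact test over 29 lists. Hspa1a and Hspa1b lie close together on chromosome 17 and share 70.1% and 68.1% of their 31-mers with other genes. Both were highest in replicate 2 and lowest in replicate 1. Il2 and Il2ra were both highest in replicate 4 and next highest in replicate 1. The test counts the members of each pair as independent, so it cannot tell whether either list varied as a group. No immediate early gene of the immediate early and heat shock list varied beyond the trend. Il17f and Bcl6 were the varying members of the Th17 effector and Tfh lists (adjusted p = 0.233 and 0.322, same Fisher's exact test), and Il2ra of the Treg list (adjusted p = 0.379). No other list held a varying gene among its tested members. The expression filter left few members of some lists to test. It kept 4 of 14 Th17 effectors and receptors, 4 of 10 Th2 genes, 1 of 10 B cell markers and 2 of 7 NK cell markers. Without 1 replicate the calls of the T cell activation list (adjusted p = 0.385 without replicate 2) and of the immediate early and heat shock list (adjusted p = 1.0 without replicate 1) ended.

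Further genes that varied beyond the trend lay outside the fixed lists. Of the 20 with the widest range, Xlr3b, Gm11175, Gm36989, Gm26514, Cfap74, Lime1, Gm42748, Gm37154 and Gm43328 are named without their levels. All of these but Gm11175 had their highest log2 CPM in replicates 1 and 3. Cdk5rap1, which modifies transfer RNA, on chromosome 2 from 154335380 to 154373010, stood at 7.34 TPM in replicate 1 against 43.5, 37.8 and 26.8 TPM in replicates 2, 3 and 4 (edgeR adjusted p = 1.7e-13). Eps8l1 stood at 8.30, 13.6, 17.7 and 32.7 TPM (adjusted p = 3.3e-09), Pdgfb, a growth factor chain, at 2.22, 1.43, 1.58 and 7.10 TPM (adjusted p = 0.00022) and the calcium pump gene Atp2b4 at 2.52, 0.527, 1.70 and 2.32 TPM (adjusted p = 9.7e-05) in the same order. The calls of Il2 (adjusted p = 0.99981), Bcl6 (0.0653), Il2ra (0.491), Il17f (0.99981), Pdgfb (0.99981) and Eps8l1 (0.336) ended without replicate 4, and that of Cdk5rap1 (0.99945) without replicate 1. Those of Hspa1a and Hspa1b ended without replicate 1 or 2, those of Il17f and Il2ra also without replicate 2, that of Il17f also without replicate 1, that of Atp2b4 without replicate 2 and that of Neat1 without replicate 3 or 4. With Holm adjustment the calls of Il17f (adjusted p = 1.0), Il2ra (0.270), Hspa1a (0.119) and Neat1 (0.116) ended as well, and Il17f was no DESeq2 dispersion outlier. The count of 94 was 60, 39, 59 and 35 without replicates 1, 2, 3 and 4.

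**Figure D3:**
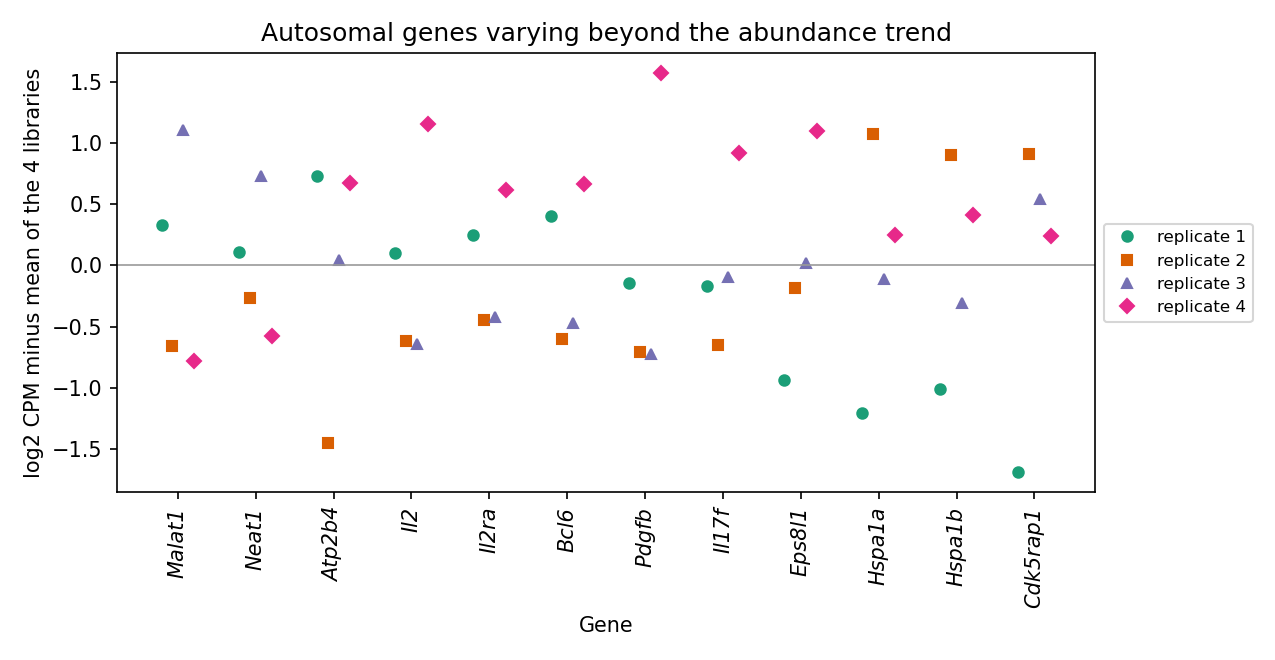
log2 CPM of each library minus the mean of the 4 libraries for 12 autosomal genes that varied beyond the abundance trend. Each symbol is 1 of the 4 Th17 libraries; Malat1 is highest in replicate 3 (795 TPM) and Cdk5rap1 lowest in replicate 1 (7.34 TPM).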

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

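All tests in this part but one were chosen only after the result was seen; the bound on histone genes was set before the data were examined. Over 211 values tested for 1 library far from the other 3, 11 had a gap above the 95% critical value of 0.83 (gap to the nearest library over the whole range), and chance gives about 11, so single gaps carry little weight.

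Gata3 stood at 17.0 TPM in replicate 3 against 13.0, 13.4 and 13.0 TPM in replicates 1, 2 and 4 (gap 0.896). Tnfrsf18 stood at 132 TPM in replicate 2 against 113, 109 and 112 TPM in the others (gap 0.835), and Ier2 at 2796 TPM in replicate 2 against 2191, 2276 and 2229 TPM (gap 0.86). Replicate 4 stood apart in Pdgfb, at 7.10 TPM against 2.22, 1.43 and 1.58 TPM (gap 0.861), and in Il22, at 1.52 TPM against 0.428, 0.221 and 0.238 TPM (gap 0.84). The difference Il17a minus Ifng on the log2(TPM + 1) scale was 2.30 in replicate 3 against 2.03, 2.03 and 2.07 (gap 0.862). The 4 counts of Il4 were all in replicate 3, the 1 count of Il5 in replicate 4 and the 1 count of Zbtb16 in replicate 1, and the list medians of NK markers in replicate 3 (0.10) and of stromal and epithelial markers in replicate 4 (0.01) were above 0 in that library alone; each of these has a gap of 1.0 by construction.

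The libraries labelled Th17 held high levels of immediate early and naive T cell genes and low levels of Th17 effectors. RNA of B, myeloid, NK, erythroid or stromal cells is argued against, since the highest median of those 5 lists was 0.0428% of the median of the T cell receptor complex list (Ighm at 138 TPM, Pecam1 at 78.6 TPM and Cd74 at 10.7 TPM were the most abundant members). Loss of fragments shared between genes is also argued against, with a median of 0.0824% of 31-mers shared over the 14 effectors and receptors. An early time after stimulation, which the 2 hour tag in the file headers may denote, stays open as a hypothesis: the list of Th17 cytokine signalling exceeded the proliferation list by at least 6.04 (log2) in every library, but resting T cells would give that too. Cells that had not entered the lineage were not tested for, and with 1 group and 1 time tag no other biological explanation was tested.

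Malat1 and genes of the TEC and sense intronic biotypes were highest in replicate 3: the biotypes took 0.114% of its counts (95% Wilson interval 0.113 to 0.116%), against 0.0835%, 0.0608% and 0.05795% in replicates 1, 2 and 4, and 145 of 201 tested genes of these biotypes were highest there. Lower depth is argued against, since replicate 4 was the shallowest library and had the lowest share (0.05795%). Genomic DNA is argued against by olfactory receptor genes, whose CPM in replicate 3 was 0.917 times that of the highest other library, and sex of the animals as the whole cause by replicate 4, which held Xist like replicate 3 but lay -0.98 SD of the 4 libraries from replicate 1. A larger share of nuclear, unspliced RNA is a candidate explanation that stays open. Ribosomal protein genes, whose mRNAs are cytoplasmic, had a median of -0.26 (log2) relative to all tested genes in replicate 3, and 0 of 79 were highest there. Levels in replicate 3 also moved with gene length. Of the 2893 shortest tested genes 21.9% were highest there, against 39.2% of the 2892 longest and 30.3% of all tested genes. An effect of length on the ribosomal protein value was not tested, so that value cannot separate nuclear RNA from a length effect. No other biological explanation was tested.

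The labels name both total and poly(A)+ RNA. Histone genes took at most 0.00451% of the counts of a library (95% Wilson interval 0.00431 to 0.00473%), below the bound of 0.1% set in advance for poly(A) selection. The 25 histone genes that share under 50% of their 31-mers took at most 0.00388%, which argues against uncounted shared fragments as the cause of the low histone share. Few cells replicating DNA may also have lowered the histones, as the median proliferation gene was at most 1.20 TPM in any library, so poly(A) selection and low replication both stay open. A bound set in advance on small RNAs was void, as Rn7sk, Rmrp, Rpph1, Rn7s1 and Rn7s2 share at least 70.2% of their 31-mers and shared fragments were not counted.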

How the results depend on the processing

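Alternatives for list members among varying genes without 1 replicate, the mean count filter and TPM without genes shorter than 200 bp were chosen after the data were seen. The count of genes at 1 TPM stayed within 1.5 times of 10895 in all 9 alternatives. The common coefficient of variation stayed within its jackknife error in the 4 alternatives of filter and normalization; the values without 1 replicate make up that error and test nothing. List contrasts kept their direction in 97 of 100 alternatives and reported pair contrasts in 48 of 48; none could pass the threshold, as 4 libraries allow no p under 0.13 and 3 none under 0.25. With only members of at least 1 TPM, Th17 effectors minus Th1 genes turned to 0.24 and minus Th2 genes to -2.77, and with the mean over members the latter was -1.15. The filter left 3 of 14 effectors, 9 of 12 Th1 genes and 4 of 10 Th2 genes, so the filtered contrasts rest on few members. Why the mean over members differed from the median was not tested.

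The 94 varying genes became 34 with Holm adjustment and 60 as DESeq2 dispersion outliers (59 shared with the 94), and 35 to 60 without 1 replicate; without replicate 3, 47 of 59 were shared. DESeq2 size factors gave 92, no filter 85, 10 counts in every library 93 and a mean count of 10 or more 110. The adjusted p of the T cell activation list was 0.571 and that of the immediate early and heat shock list 0.113 with the top 5% of genes by deviance. Without 1 replicate they ranged from 0.0152 to 1.0 and from 0.000367 to 1.0: the activation call ended without replicates 2 (0.385) and 4, the other without replicates 1 and 2. Percentiles moved with the background of genes above 0.1 TPM (Th17 regulators 99.96, effectors 0.29, proliferation 0.21) and with CPM (effectors 41.2, proliferation 69.8). The mitochondrial share was 5.61% of TPM. Mean Pearson correlation was 0.978 among genes of at least 1 TPM and 0.982 with a pseudocount of 0.1, and mean Spearman correlation 0.980 among genes of at least 1 TPM. Leaving out 1 of 4 libraries cannot move a mean TPM by 1 SD, and leaving out short genes scales all genes of a library alike, so neither tests the mean TPM of a named gene. Posterior mean TPM was not run, as the files hold counts. Depth limits genes of few counts, such as Il22 (23), Il23r (11) and Il4 (4). No pairing of samples between groups was possible because there is 1 group. The list and gene pair contrasts were paired within each library.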

Other observations

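The genes in this part from outside the fixed lists were chosen for their high levels after these were seen, so their values describe no gene group. Nr4a3 stood at 3837 ± 486 TPM and Nr4a2 at 1512 ± 206 TPM (SD, n = 4), beside Btg2 at 3403 ± 295 TPM, Nfkbid at 3204 ± 304 TPM, Csrnp1 at 2001 ± 143 TPM, Gadd45b at 1419 ± 51.7 TPM and Zfp36 at 1398 ± 132 TPM. Socs1, which encodes an inhibitor of cytokine signalling, stood at 1883 ± 196 TPM, Nfkbia at 1049 ± 48.6 TPM, Dusp5 at 1047 ± 102 TPM and Dusp2 at 958 ± 153 TPM. The cytokine gene Tnf stood at 712 ± 111 TPM, above Il2 (23.1 ± 14.2 TPM) and Il17a (5.65 ± 1.20 TPM) in 4 of 4 libraries.

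Among GTPase genes, Gimap6 stood at 2295 ± 374 TPM, Gimap4 at 2001 ± 268 TPM and Gimap3 at 1771 ± 440 TPM, and the interferon-induced Igtp at 1124 ± 54.8 TPM and Ifi47 at 1128 ± 100.1 TPM. Gimap3 and Igtp share 15.0% and 15.9% of their 31-mers with other genes. All 4 libraries carry 1 donor identifier in the labels and sex is marked as not collected, while Ddx3y stood at 305 and 213 TPM in replicates 1 and 2 against 0.914 and 1.39 TPM in replicates 3 and 4 and Xist at 0.791 and 0.602 TPM against 142 and 76.5 TPM. The 4 libraries therefore did not all come from 1 animal.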
